A study of Mus musculus with 22 samples.

How the data were processed

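Liver of female C3H mice was sampled by microdissection, RNA was labelled by amplification to biotin cRNA, and each sample was hybridised to an Illumina mouse bead array with 45281 probes, per the labels. The 22 arrays comprised 3 controls given vehicle, 3 samples at 28 weeks and 7 at 42 weeks of TCPOBOP (3 mg/kg once a week), and 9 samples at 28 weeks of TCPOBOP after DENA (90 mg/kg, once). Groups and replicate numbers were taken from the sample titles, and slides from the array positions. The controls carry only an abbreviation in their titles, which was read as the vehicle group because the protocol names no other group without TCPOBOP. A further protocol of the study, with earlier time points, was not analysed here. Each slide held arrays of 2 or 3 groups: slide 1 all but controls, slide 2 all but DENA plus TCPOBOP, slide 3 controls and DENA plus TCPOBOP, and slide 4 all but TCPOBOP 42 weeks.

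The deposited tables hold intensity values and detection p-values. Per the labels the arrays were read out with BeadStudio 3.0.19.0. In the non-normalized table the authors give summarised probe intensity on a linear scale, with no background subtracted, as seen from the absence of values at or below 0. In the authors' normalized table all arrays have the same minimum and maximum intensity, which points to quantile normalization, but the method is not stated. The deposited series values equal that table. Each detection p-value, as deposited, ranks a probe against the negative control beads of its array. The non-normalized intensities were used, and the normalized ones served as an alternative.

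Background was corrected with the normexp model of limma 3.58.1, its negative controls inferred from the detection p-values, with an offset of 16, followed by quantile normalization on the log2 scale in R 4.3.3. Probes with a detection p under 0.05 on at least 3 arrays were kept (22622). Probes were named from the platform annotation deposited with the arrays, with current symbols from the RefSeq gene table where it holds the probe's Entrez number. The annotation gives 1 gene symbol to 34885 probes, several to 18 and none to 10378. Of the kept probes 19067 had 1 symbol. A gene was represented by its brightest kept probe, leaving 11975 genes, 4739 of them with more than 1 probe. Probes of close paralogues (Hamp and Hamp2, Gsta1 and Gsta2, the Mup, Gstp, Bglap and Saa families) may bind each other's RNA, so those names stand for the family. Between 34.8% and 42.6% of probes were detected per array.

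All 4 groups were fitted together with limma's lmFit and eBayes, and 6 contrasts were drawn: each treated group against controls, and the treated groups against each other. P-values were adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes of genes undetected in a whole group are given as lower limits, against the lowest detected signal. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Members were also adjusted over the list alone. Alternatives estimated the correlation or used fry. Principal components used centred log2 values. Figures were drawn with matplotlib 3.10.9, and tables summarised with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

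Comparisons, thresholds, gene lists, most alternatives and the rule for naming genes were chosen before the data were examined. The rule takes, in each comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap, leaving out unnamed loci and genes whose probes disagree in sign. It adds up to 3 members of each list described (the largest changes among called members, or the smallest p), and Ctnnb1, Glul, Axin2, Lgr5, Tbx3, Cyp2e1, Cyp1a2, Cyp2b10, Cyp2c55, Afp, Gpc3 and Nr1i3 throughout. Mki67 was planned as well, but had no kept probe. From the genes so chosen the text names a part, picked after their values were seen and favouring genes whose call held when arrays were left out or settings changed. Of the named genes called in each comparison, the number that lose the call when some array is left out is 14 of 46 for 28 weeks against controls, 7 of 66 for 42 weeks against controls, 5 of 67 for DENA plus TCPOBOP against controls, 18 of 56 for 42 against 28 weeks, 16 of 55 for DENA plus TCPOBOP against 28 weeks and 6 of 17 against 42 weeks.

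Alternatives replaced one choice at a time: the authors' normalized values or the series values, no background correction, cyclic loess or median scaling, no filter or a stricter filter on dim probes, the mean of a gene's probes, slide as a fixed or random block, replicate number as a block, only the groups compared, array weights, moderation with trend and robust fitting, and each array of the groups compared left out in turn. For gene lists, cyclic loess, median scaling, no background correction and left-out arrays were added after seeing the data. The replicate numbers were tested for pairing. After removing group means, arrays of the same number correlated at a median r of 0.0180 (-0.145 to 0.136). The labels do not link samples across groups, so beside that block no paired test was run. Slides explained a median of 18.9% of a gene's variance within groups, where unrelated slides would give 16.7%, and arrays of a slide correlated at 0.0394 (duplicateCorrelation, statmod 1.5.0).

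The overlap of calls that share controls was compared with 50 simulations that drew the treated groups and the controls from the residual spread, whereas the plan had been to keep the real controls. The fit was tested on simulated data with 200 changed genes: it recovered 4% to 16% of changes of 0.5 on the log2 scale, 44% to 90% of 1, 80% to 100% of 2 and 98% to 100% of 4 across the comparisons, with 5 to 12 false calls. In simulated data with 1 shifted list, camera called that list and no other. Both kinds of simulation drew genes independently, so they do not test the assumed correlation between list members. Probes without a gene symbol were tested apart and appear in no gene or list.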

Results

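Gene expression was measured in 22 liver samples of female C3H mice, 1 bead array per sample, in a study of liver tumours that arise under TCPOBOP, an agonist of the constitutive androstane receptor (CAR) that does not damage DNA. The samples formed 4 groups: 3 controls that had received vehicle, 3 samples after 28 weeks of weekly TCPOBOP, 7 samples after 42 weeks of weekly TCPOBOP, and 9 samples after a single dose of the DNA-damaging carcinogen diethylnitrosamine (DENA) followed by 28 weeks of TCPOBOP. Per the labels, hepatocellular carcinomas were seen in both regimens at these times, and RNA came from microdissected tissue. They call the samples of a group biological replicates, but do not say which sample was tumour, how old each control was, or whether each array came from its own mouse. If samples shared a mouse, the p-values below measure only the spread between these samples and may be too small. Between 34.8% and 42.6% of the 45281 probes on an array gave a signal above the negative control beads, with the lowest share on slide 2 (34.8% to 38.0%), and 11975 genes were tested.

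The first principal component, which held 39.5% of the variance, separated controls, TCPOBOP 28 weeks and the other arrays, while TCPOBOP 42 weeks and DENA plus TCPOBOP overlapped. Controls lay at 74.4 to 80.9, TCPOBOP 28 weeks at 35.1 to 38.9 and TCPOBOP 42 weeks at -37.8 to -9.28. The DENA plus TCPOBOP samples lay at -31.6 to -7.34 except replicate 6, at 17.1. Between arrays of a group, Pearson r across genes was 0.980 to 0.989 among controls, 0.985 to 0.988 at 28 weeks of TCPOBOP, 0.943 to 0.971 at 42 weeks and 0.944 to 0.978 in DENA plus TCPOBOP. Genes are not independent replicates, so no p is given. Below, changes are log2 fold changes ± standard error with limma's adjusted p, and levels are mean log2 signals ± SD. The number of arrays, n, is 3, 3, 7 and 9 in the order given above. A value after a left-out array or another setting is the adjusted p there. Values of the called genes named below did not overlap between the groups compared, except in some comparisons for Afp, Axin2, C4b, Gpc3, Igf1, Sp5 and Tbx3. The size of a change is uncertain where background sets the lower level, as for Afp, Aldh3a1, Bdh2, Car1, Cxcl10, Cyp2d12, Gpc3, Hkdc1 and Slc1a2, each detected on a minority of the arrays of a group compared.

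Of 38 gene lists fixed before the data were examined, 26 were called at least once, in 76 calls over 6 comparisons. Lists were tested with camera, which asks whether a list's members lie higher or lower than all other genes and here assumed a correlation of 0.01 between members. With the correlation estimated from the arrays only 6 of the 76 calls held: CAR targets in each regimen against controls, NRF2 targets at 42 weeks and in DENA plus TCPOBOP, and oncofetal genes in DENA plus TCPOBOP. With fry, which asks whether the list moved at all, 63 held. List results below are therefore given with both camera values, and with fry's where fry changed the call. Lists can share members, such as Gstm3 among CAR targets and pericentral genes, so their calls need not be separate findings. Ranges over the alternatives leave out the estimated correlation and fry.

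**Figure D1:**
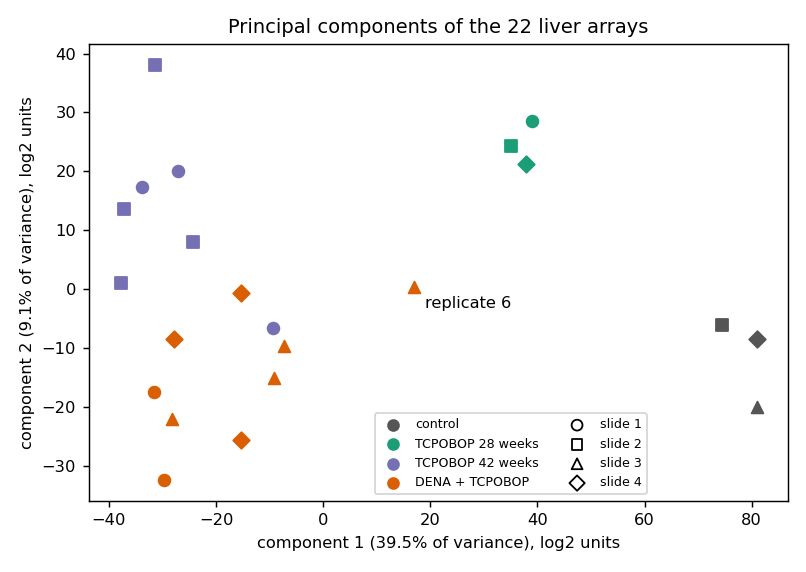
Principal components of the 22 arrays, in log2 units. Each point is an array, its colour the group and its shape the slide. Component 1 holds 39.5% of the variance and separates the controls, at 74.4 to 80.9, from every treated array.

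After 28 weeks of TCPOBOP without DENA, liver had more RNA of drug-metabolising enzymes that CAR controls. Cyp2b10, the cytochrome P450 most often used to read CAR activity, rose by 1.66 ± 0.15, Cyp2c55 by 3.43 ± 0.25 and the glutathione transferase Gstm3 by 4.16 ± 0.31. Cyp2b10 was already bright in controls (13.49 ± 0.18) and near the top of the scale after TCPOBOP (15.15 ± 0.18), where the array compresses differences. Chil1, which encodes a chitinase-like protein, was detected on no control array and rose at least 121-fold. The largest falls included Avpr1a, the liver's vasopressin receptor (-6.35 ± 1.13), the cytochrome P450 Cyp3a41b (-4.72 ± 0.23) and the sulfotransferase Sult2a8 (-4.27 ± 0.50).

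Of 33 measured CAR target genes, 19 rose and 0 fell (23 and 1 adjusted over the list alone), with a higher list mean on 3 of 3 arrays (adjusted p = 9.99e-26, and adjusted p = 0.000274 with an estimated correlation). Within slides the list's median change was 1.25 on slide 2 and 0.95 on slide 4. Targets of NRF2, the regulator of antioxidant defence, were also higher. Of 19, 6 rose and 0 fell (9 and 0 adjusted over the list alone), led by the glutathione transferases Gsta2 (4.83 ± 0.52) and Gsta1 (4.78 ± 0.48) and the transporter Abcc4 (3.11 ± 0.32). That list gave adjusted p = 5.21e-08, and adjusted p = 0.0694 with an estimated correlation. Cell cycle genes were higher as a list (adjusted p = 2.57e-12, and adjusted p = 0.246 with an estimated correlation), and of 29 measured, 11 rose and 0 fell (14 and 0 adjusted over the list alone). Among them were Cdc20, an activator of the anaphase-promoting complex (2.95 ± 0.54), and Rrm2, a subunit of ribonucleotide reductase that was detected on no control array and rose at least 5.63-fold.

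Markers of Kupffer cells and macrophages were higher. Of 19, 6 rose and 0 fell (8 and 0 adjusted over the list alone, list adjusted p = 1.60e-07, adjusted p = 0.183 with an estimated correlation). Cd14, a co-receptor for bacterial lipopolysaccharide, rose by 2.21 ± 0.45. So were MHC class II antigen presentation genes. Of 10, 4 rose and 0 fell (6 and 0 adjusted over the list alone, list adjusted p = 3.02e-05, adjusted p = 0.352 with an estimated correlation). Interferon response genes were higher as a list (adjusted p = 0.00126, and adjusted p = 0.551 with an estimated correlation and 0.118 with fry). Of 21, 3 rose and 0 fell (5 and 0 adjusted over the list alone), among them the chemokine Cxcl10 (2.84 ± 0.58). The urea cycle and amino acid list was lower. Of 26, 0 rose and 1 fell (0 and 1 adjusted over the list alone, list adjusted p = 0.00171, adjusted p = 0.551 with an estimated correlation and 0.118 with fry). The member that fell was Cbs, which makes cystathionine (-1.37 ± 0.28).

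Targets of β-catenin, the transcriptional co-activator of the Wnt pathway, were lower at 28 weeks. Of 16 measured members, 1 rose and 5 fell (2 and 9 adjusted over the list alone), and the list mean was lower on 3 of 3 arrays. Notum, a secreted Wnt inhibitor, fell by 2.72 ± 0.64. Tbx3, a transcription factor that β-catenin induces in liver tumours, stood at 9.48 ± 0.74 in controls and 7.51 ± 0.30 after TCPOBOP (-1.96 ± 0.47, adjusted p = 0.0122), a call that ended without TCPOBOP 28 weeks replicate 1 (0.0661) or control replicate 2 (0.101). Lgr5, the R-spondin receptor, was detected on 3 of 3 control arrays and 0 of 3 TCPOBOP arrays, and was at least 2.22-fold lower (adjusted p = 0.0493). That call ended without any 1 array of either group (0.0746 to 0.214) and on the authors' normalized values (0.132, range 0.00275 to 0.132 over the alternatives). Glutamine synthetase (Glul) changed by -1.80 ± 0.72 (adjusted p = 0.164) and Axin2, a feedback inhibitor of the pathway, by -1.67 ± 0.70 (adjusted p = 0.191), neither past the threshold. Both passed when only these groups were fitted (Glul 0.00212, range 0.00212 to 0.307, Axin2 0.00199, range 0.00199 to 0.413). RNA of β-catenin itself, Ctnnb1, changed by -0.19 ± 0.22 (adjusted p = 0.731). The list gave adjusted p = 0.00913, and adjusted p = 0.581 with an estimated correlation and 0.145 with fry. With slide as a block it gave 0.00265. It was not called on the authors' normalized values (0.0684) or without background correction (0.0711), in a range of 0.000311 to 0.0711 over the alternatives. Within slides its median change was -1.69 on slide 2 and -1.03 on slide 4.

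Oncofetal and liver tumour genes were higher as a list at this time, by an unstable call, while Afp and Gpc3 did not rise. Afp, which encodes alpha-fetoprotein, was at 5.26 ± 1.07 in controls and 5.02 ± 0.21 after TCPOBOP, detected on 1 of 3 arrays in both groups, and the oncofetal glypican Gpc3 was at 5.58 ± 0.22 and 5.03 ± 0.12. Golm1, which encodes a Golgi membrane protein, did rise (2.55 ± 0.36). Of 17 genes in the list, 4 rose and 0 fell (4 and 0 adjusted over the list alone, list adjusted p = 0.0199, adjusted p = 0.477 with an estimated correlation and 0.106 with fry). The call ended without control replicate 2 (0.05 when rounded) and on the authors' normalized values (0.0874, range 0.0120 to 0.0889 over the alternatives). RNA of CAR itself, Nr1i3, fell by 1.89 ± 0.33 on its brightest probe, while 2 of its 4 other probes pointed the other way. Cyp2e1, a cytochrome P450 of the hepatocytes around the central vein, changed by -0.14 ± 0.25 (adjusted p = 0.840). Cyp1a2, another of them, rose by 0.99 ± 0.23 (adjusted p = 0.00780), a call lost under cyclic loess (0.0898) and median scaling (0.0812, range 0.000128 to 0.0898 over the alternatives). Cyp2e1 lay near the top of the scale (14.85 on its lowest array at 42 weeks), where differences are compressed. Its small changes here and in the comparisons below may therefore understate a difference.

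In all, 703 genes passed the threshold, 462 higher and 241 lower, and 682 passed with slide as a block. Of the called genes, 99.9% on slide 2 (1 against 1 arrays) and 100% on slide 4 (1 against 1 arrays) kept their sign. Here and in the comparisons below, the genes were called on these same arrays. Such agreement is therefore built in and cannot decide on a slide effect. With median scaling in place of quantile normalization the share of called genes that were higher went from 65.7% to 79.0%. The count was 441 and 454 without TCPOBOP 28 weeks replicates 1 and 3, and 448 without control replicate 2.

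After 42 weeks of TCPOBOP, when the labels report tumours under the agonist alone, the same drug-metabolism genes were high, oncofetal genes were high as well, and genes of the periportal hepatocyte were low. Ly6d, which encodes a small membrane-anchored surface protein, rose by 6.40 ± 0.83, Gpc3 by 4.43 ± 1.16 and Afp by 3.03 ± 0.67. Aldh3a1, an aldehyde dehydrogenase scarce in normal liver, rose by 7.02 ± 0.75 and the hexokinase-like gene Hkdc1 by 6.72 ± 0.32. The iron-regulating hormone hepcidin was lower (Hamp -7.08 ± 1.32), as were A1bg (-9.10 ± 1.62), the cytochrome P450 Cyp4f14 (-7.50 ± 0.80) and the betaine-homocysteine methyltransferase Bhmt (-7.09 ± 0.98), the last 3 detected on 4, 4 and 4 of 7 TCPOBOP arrays. Ptpn14 and Chil1 were detected on no control array and rose at least 66.5-fold and 102-fold.

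CAR target genes were higher on 7 of 7 arrays. Of 33, 22 rose and 2 fell (23 and 3 adjusted over the list alone, list adjusted p = 2.07e-11, adjusted p = 0.0234 with an estimated correlation), with a median change of 1.26 on slide 2. Cyp2b10 rose by 1.70 ± 0.13, Cyp2c55 by 3.42 ± 0.21, Gstm3 by 4.85 ± 0.26 and Cyp1a2 by 1.67 ± 0.19. Of 19 NRF2 targets, 14 rose and 0 fell (15 and 0 adjusted over the list alone, list adjusted p = 3.46e-10, adjusted p = 0.0412 with an estimated correlation). They included the carbonyl reductase Cbr3 (4.31 ± 0.61), and Gpx2 and the cystine transporter Slc7a11, which were detected on no control array and rose at least 20.9-fold and 14.1-fold. Oncofetal and tumour genes were higher on 7 of 7 arrays. Of 17, 12 rose and 0 fell (12 and 0 adjusted over the list alone), among them Golm1 (4.78 ± 0.30) and the imprinted gene Peg3 (4.53 ± 0.39). This list gave adjusted p = 9.07e-07, and adjusted p = 0.0520 with an estimated correlation. Cell cycle genes rose in number too, with Cdc20 at 3.71 ± 0.46 and Rrm2 at least 6.48-fold higher. Of 29, 22 rose and 0 fell (24 and 0 adjusted over the list alone, list adjusted p = 2.62e-10, adjusted p = 0.208 with an estimated correlation). Glycolysis genes were higher as a list (adjusted p = 0.00536, and adjusted p = 0.187 with an estimated correlation), and of 13, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with aldolase A (Aldoa) up by 1.69 ± 0.21.

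Periportal genes were lower on 7 of 7 arrays. Of 14, 0 rose and 11 fell (0 and 12 adjusted over the list alone, list adjusted p = 1.57e-05, adjusted p = 0.244 with an estimated correlation), with Etnppl at -5.26 ± 0.55, the cytochrome P450 Cyp2f2 at -5.11 ± 0.92 and a list median of -3.12 on slide 2. The urea cycle and amino acid list followed. Of 26, 0 rose and 16 fell (0 and 20 adjusted over the list alone, list adjusted p = 1.45e-07, adjusted p = 0.187 with an estimated correlation), including Bhmt, histidine ammonia-lyase Hal (-3.19 ± 0.67) and tyrosine aminotransferase Tat (-3.12 ± 0.57). Complement and other secreted hepatocyte proteins were lower (adjusted p = 2.07e-05, and adjusted p = 0.187 with an estimated correlation), and of 28, 0 rose and 16 fell (0 and 17 adjusted over the list alone), with C9 at -5.80 ± 1.18 and C4b at -4.10 ± 0.68. Oxidative phosphorylation genes showed smaller falls, such as the succinate dehydrogenase subunits Sdhb (-1.43 ± 0.23) and Sdhd (-1.29 ± 0.30). Of 29, 0 rose and 15 fell (0 and 18 adjusted over the list alone, list adjusted p = 2.04e-05, adjusted p = 0.208 with an estimated correlation). Genes with male-biased expression in liver were lower (adjusted p = 0.0154, and adjusted p = 0.333 with an estimated correlation), and of 20, 1 rose and 9 fell (2 and 9 adjusted over the list alone), with the major urinary protein Mup3 at -5.86 ± 1.28. Endothelial markers were lower as well (adjusted p = 0.00698, and adjusted p = 0.495 with an estimated correlation). Of 24, 1 rose and 11 fell (2 and 12 adjusted over the list alone), with Gpr182 at -3.39 ± 0.54 and Oit3 at -3.14 ± 0.49.

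The β-catenin list did not differ from other genes at 42 weeks. Of 16 members, 2 rose and 2 fell (2 and 0 adjusted over the list alone), and the list gave adjusted p = 0.913, and adjusted p = 0.965 with an estimated correlation, with a median change of -0.38, a mean of -0.18 and a test that pointed upward. The members that rose were the dicarboxylate transporter Slc13a3 (2.82 ± 0.28) and Tnfrsf19 (1.92 ± 0.29). Glul was at 8.46 ± 1.14 against 8.88 ± 0.51 in controls (adjusted p = 0.640), Axin2 at 7.58 ± 0.65 against 7.28 ± 0.53 (adjusted p = 0.743), and Lgr5 changed by -0.38 ± 0.40 (adjusted p = 0.503). Tbx3 was at 8.43 ± 0.55 (-1.05 ± 0.40, adjusted p = 0.0488). That call ended without TCPOBOP 42 weeks replicates 1 (0.0798), 4 (0.0632), 5 (0.0564), 6 (0.0514) or 7 (0.0898) or control replicates 1 (0.0896) or 2 (0.329), the change itself being -0.65 without control replicate 2, and on the authors' normalized values (0.0577, range 0.0408 to 0.208). Ctnnb1 changed by -0.37 ± 0.18 (adjusted p = 0.131), passing only under cyclic loess (0.0336, range 0.0336 to 0.536). Pericentral genes moved both ways and were not called as a list. Of 19, 9 rose and 5 fell (9 and 5 adjusted over the list alone, list adjusted p = 0.0585, adjusted p = 0.504 with an estimated correlation and 0.00139 with fry), with Gstm3 rising, Avpr1a falling (-4.74 ± 0.95) and Cyp2e1 at 0.10 ± 0.21 (adjusted p = 0.761). The pericentral list passed with the replicate number as a block (0.0498) and with no filter on dim probes (0.0164, range 0.0164 to 0.112). It also passed without TCPOBOP 42 weeks replicate 7 (0.0448) or control replicate 3 (0.0398).

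Among hepatocyte transcription factors Cebpa fell by 2.08 ± 0.39 and Prox1 by 1.86 ± 0.22, and CAR itself (Nr1i3) by 0.96 ± 0.28 on the brightest of its probes (0.0594 with the replicate number as a block, range 0.00134 to 0.0594). Of 16, 1 rose and 7 fell (2 and 7 adjusted over the list alone, list adjusted p = 0.0444, adjusted p = 0.187 with an estimated correlation), a call that ended without TCPOBOP 42 weeks replicates 4 (0.0571) or 5 (0.0514) or control replicate 2 (0.0502). Red blood cell markers were lower by a similarly thin margin. Of 10, 0 rose and 3 fell (0 and 5 adjusted over the list alone, list adjusted p = 0.0444, adjusted p = 0.333 with an estimated correlation), with the carbonic anhydrase Car1 at -3.61 ± 0.27, and the call ended without TCPOBOP 42 weeks replicates 4 (0.0612), 6 (0.0557) or 7 (0.0578) or control replicate 1 (0.0638) and on the authors' normalized values (0.0551, range 0.0146 to 0.0556). In all, 3872 genes passed the threshold, 1813 higher and 2059 lower, and 2821 passed with slide as a block. Of the called genes, 99.8% on slide 2 (4 against 1 arrays) kept their sign.

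In DENA plus TCPOBOP, the regimen that starts with a DNA-damaging carcinogen, liver differed from controls in the same directions as after 42 weeks of TCPOBOP. Oncofetal genes were high: Ly6d rose by 5.98 ± 0.80, the fetal growth factor Igf2 by 5.33 ± 1.15, Gpc3 by 5.16 ± 1.12 and Afp by 3.06 ± 0.65. Ptpn14 and Chil1 were detected on no control array and rose at least 61.2-fold and 66.6-fold. Large falls were those of A1bg (-7.53 ± 1.57) and Cyp4f14 (-6.73 ± 0.77), detected on 7 and 8 of 9 arrays. The melanin-synthesis gene Dct and Sult2a8 fell to background, detected on 1 and 2 of 9 arrays.

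Of 33 CAR target genes, 22 rose and 2 fell (23 and 3 adjusted over the list alone, list adjusted p = 5.13e-13, adjusted p = 0.0126 with an estimated correlation), with a higher list mean on 9 of 9 arrays and medians of 1.09 on slide 3 and 0.83 on slide 4. Cyp2b10 rose by 1.76 ± 0.13, Cyp2c55 by 3.37 ± 0.20 and Gadd45b, a stress-response gene that CAR induces, by 4.53 ± 0.40. Of 19 NRF2 targets, 16 rose and 0 fell (16 and 0 adjusted over the list alone, list adjusted p = 4.24e-11, adjusted p = 0.0268 with an estimated correlation), and Gpx2 rose at least 20.4-fold. The oncofetal list held with an estimated correlation too (adjusted p = 1.55e-07, and adjusted p = 0.0320 with an estimated correlation). Of 17, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with medians of 2.77 on slide 3 and 3.62 on slide 4. Cell cycle genes were higher as a list (adjusted p = 3.96e-08, and adjusted p = 0.307 with an estimated correlation), and of 29, 16 rose and 0 fell (20 and 0 adjusted over the list alone), including Cdc20 (2.70 ± 0.44) and the transcription factor E2f1 (2.23 ± 0.25). Of 13 glycolysis genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, list adjusted p = 0.0192, adjusted p = 0.307 with an estimated correlation), with Aldoa at 1.87 ± 0.21. Interferon response genes (adjusted p = 0.0192, and adjusted p = 0.450 with an estimated correlation) included Cxcl10 at 2.75 ± 0.47 and Oas1g at 2.87 ± 0.35. Of 21, 6 rose and 1 fell (6 and 1 adjusted over the list alone), and the list gave 0.0586 with slide as a block (range 0.000238 to 0.0586 over the alternatives). Hypoxia genes such as P4ha2 (2.18 ± 0.40) and Egln3 (1.80 ± 0.23) were higher (adjusted p = 0.0439, and adjusted p = 0.396 with an estimated correlation). Of 17, 7 rose and 1 fell (7 and 2 adjusted over the list alone). The call ended with slide as a block (0.0575, range 0.0164 to 0.0575), on the authors' normalized values (0.0563) and without DENA plus TCPOBOP replicates 2 (0.0518), 6 (0.0563) or 9 (0.0551) or control replicate 1 (0.0505).

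Periportal genes were lower, with Cyp2f2 at -5.14 ± 0.89, Etnppl at -4.86 ± 0.53 and Igf1 at -3.46 ± 0.61. Of 14, 1 rose and 10 fell (1 and 12 adjusted over the list alone, list adjusted p = 9.08e-06, adjusted p = 0.307 with an estimated correlation), and medians were -1.90 on slide 3 and -2.10 on slide 4. Of 26 urea cycle and amino acid genes, 0 rose and 17 fell (0 and 18 adjusted over the list alone, list adjusted p = 1.84e-07, adjusted p = 0.300 with an estimated correlation), with Bhmt at -5.73 ± 0.95 and the glycine methyltransferase Gnmt at -2.35 ± 0.44. Complement and other secreted proteins were lower (adjusted p = 0.000143, and adjusted p = 0.307 with an estimated correlation). Of 28, 0 rose and 12 fell (0 and 16 adjusted over the list alone), with C9 at -4.97 ± 1.14. Oxidative phosphorylation genes were lower as a list (adjusted p = 0.000148, and adjusted p = 0.307 with an estimated correlation), and of 29, 0 rose and 7 fell (0 and 7 adjusted over the list alone), with Sdhb at -1.20 ± 0.22. Male-biased genes followed (adjusted p = 0.00665, and adjusted p = 0.307 with an estimated correlation), and of 20, 1 rose and 9 fell (1 and 9 adjusted over the list alone), with Mup3 at -6.13 ± 1.24.

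Endothelial and matrix markers were lower in the same samples, which was not so for Kupffer cell and macrophage markers (list adjusted p = 0.150, pointing higher). Of 24 endothelial markers, 0 rose and 14 fell (0 and 14 adjusted over the list alone, list adjusted p = 0.000188, adjusted p = 0.331 with an estimated correlation), with Ehd3 at -2.77 ± 0.50 and the Wnt ligand Wnt2 falling to background, detected on 3 of 9 arrays. Of 27 extracellular matrix and stellate cell markers, 3 rose and 11 fell (3 and 13 adjusted over the list alone, list adjusted p = 0.0106, adjusted p = 0.450 with an estimated correlation), with Ecm1 at -3.11 ± 0.56 and Reln at -2.85 ± 0.72. Genes that respond to tissue handling were higher (adjusted p = 0.00291, and adjusted p = 0.450 with an estimated correlation). Of 16, 6 rose and 0 fell (9 and 0 adjusted over the list alone), with Jun at 2.93 ± 0.31 and Atf3, detected on no control array, at least 9.79-fold higher. That list's mean was above the control mean on 9 of 9 arrays. Pericentral genes, the other end of the liver lobule, were higher as a list (adjusted p = 0.00665, and adjusted p = 0.341 with an estimated correlation). Of 19, 9 rose and 3 fell (10 and 3 adjusted over the list alone), with Gstm3 at 4.88 ± 0.25, the amino acid transporter Slc1a4 at 2.09 ± 0.46 and Cyp1a2 at 1.74 ± 0.19, while Cyp2e1 changed by 0.08 ± 0.20 (adjusted p = 0.807). CAR itself (Nr1i3) was at -0.82 ± 0.27 (adjusted p = 0.0243), a call that ended without control replicates 1 (0.103), 2 (0.0697) or 3 (0.0602) and with the replicate number as a block (0.232, range 0.00266 to 0.232).

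The β-catenin list stayed just outside the threshold (adjusted p = 0.0686, and adjusted p = 0.559 with an estimated correlation). Of 16 members, 2 rose and 0 fell (2 and 0 adjusted over the list alone), the risers being Slc13a3 (3.14 ± 0.28) and Tnfrsf19 (2.04 ± 0.28). Its median change was 0.30 and, within slides, 0.14 on slide 3 and 0.70 on slide 4. Glul reached 10.07 ± 1.04 against 8.88 ± 0.51 in controls (adjusted p = 0.148) and Axin2 8.35 ± 1.28 against 7.28 ± 0.53 (adjusted p = 0.182). Both passed with array weights (Glul 0.0231, range 0.0231 to 0.275, Axin2 0.0218, range 0.0218 to 0.276), and Axin2 also without DENA plus TCPOBOP replicate 6 (0.0121). Lgr5 changed by 0.36 ± 0.38 (adjusted p = 0.550), Tbx3 by 0.26 ± 0.39 (adjusted p = 0.673) and Ctnnb1 by -0.21 ± 0.18 (adjusted p = 0.430). The list passed with the replicate number as a block (0.00985), no filter on dim probes (0.0318) and median scaling (0.0363). It also passed with no background correction (0.0452) and on the authors' normalized values (0.0456), but not with slide as a block (0.0794, range 0.00985 to 0.0794). Among left-out arrays, it passed without DENA plus TCPOBOP replicates 6 (0.0132) or 8 (0.0357) or control replicates 1 (0.0482) or 2 (0.0473). In all, 3174 genes passed the threshold, 1456 higher and 1718 lower, and 3253 passed with slide as a block. Of the called genes, 99.9% on slide 3 (4 against 1 arrays) and 99.8% on slide 4 (3 against 1 arrays) kept their sign.

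**Figure D2:**
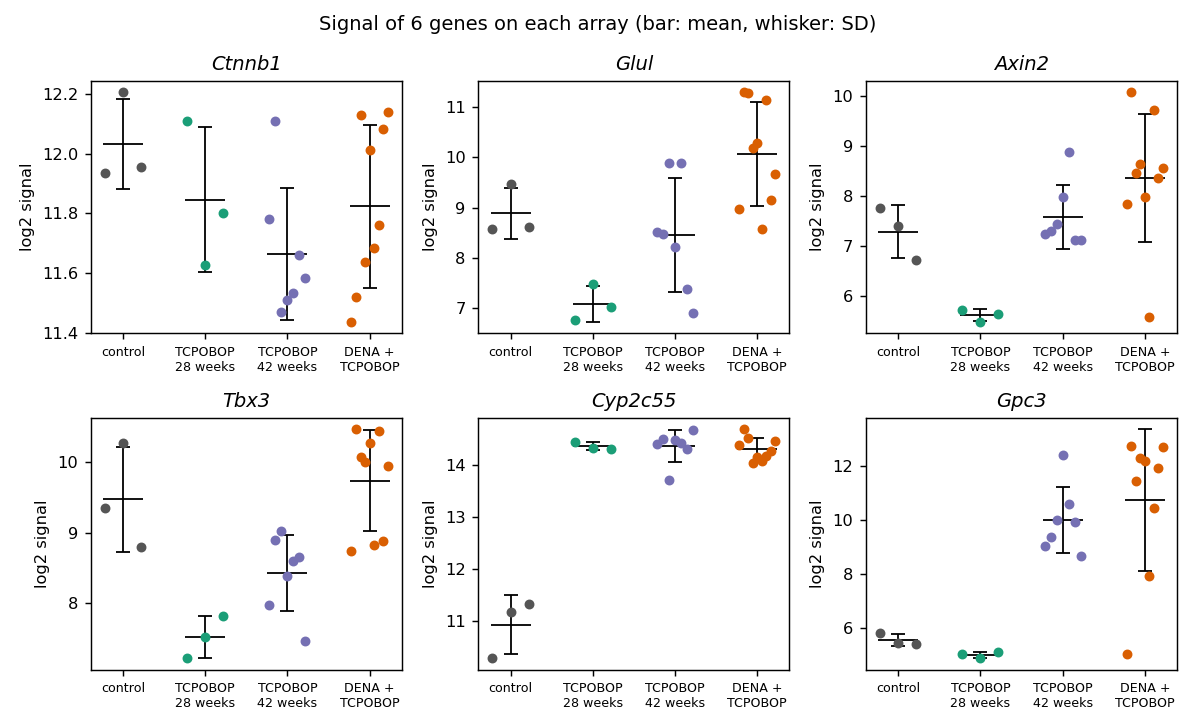
Log2 signal of 6 genes on each array, by group. Points are arrays, bars the group mean and whiskers the SD. Cyp2c55 has its lowest mean in controls (10.93 ± 0.56), and Glul, Axin2 and Tbx3 have theirs at 28 weeks of TCPOBOP (7.09 ± 0.36, 5.61 ± 0.12 and 7.51 ± 0.30).

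The regimens changed many genes in common. Of the genes called against controls, 2639 were shared by 42 weeks of TCPOBOP and DENA plus TCPOBOP, 1207 higher in both and 1432 lower in both, among them Ly6d, Golm1, Cdc20 and Gstm3 on the higher side and Cyp2f2, Bhmt, C9 and Mup3 on the lower. Independent calls would share 516, and 0 genes were called in opposite directions. At 28 weeks TCPOBOP shared 622 calls with TCPOBOP at 42 weeks (407 higher and 215 lower, 2 opposite, 111 under independence) and 579 with DENA plus TCPOBOP (378 higher and 201 lower, 2 opposite, 90.8 under independence). These comparisons used the same 3 controls, which alone makes fold changes alike. Across genes r was 0.940, 0.729 and 0.710, against a mean of 0.724, 0.593 and 0.613 in 50 simulations of unchanged groups with shared controls. In covariance, the excess over those simulations was 0.814, 0.434 and 0.374. The largest simulated overlap of calls was 0, but unchanged groups give almost no calls. It therefore does not measure how far shared controls raise the overlap among real calls. The 3 controls were too few to be halved, so part of the shared change may come from them.

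At 42 weeks of TCPOBOP alone against 28 weeks, oncofetal genes were higher and periportal genes lower. Gpc3 was 31.4-fold higher at 42 weeks (4.97 ± 1.16), Afp rose by 3.27 ± 0.67, Ly6d by 4.89 ± 0.83 and the osteocalcin gene Bglap2 by 5.19 ± 0.69. Hepcidin fell furthest (Hamp2 -7.51 ± 1.41, Hamp -6.10 ± 1.32), with Cyp2d12 (-5.56 ± 0.92), the hydroxybutyrate dehydrogenase Bdh2 (-5.56 ± 0.81) and carbonic anhydrase 3 (Car3 -5.23 ± 0.97). Between these times no difference passed for Cyp2b10 (0.04 ± 0.13, adjusted p = 0.879), which lay near the top of the scale where differences are compressed, or for Cyp2c55 (-0.0039 ± 0.21, adjusted p = 0.993).

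Of 17 oncofetal genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone, list adjusted p = 1.22e-06, adjusted p = 0.134 with an estimated correlation), with medians of 2.04 on slide 1 and 1.41 on slide 2. Of 14 periportal genes, 0 rose and 9 fell (0 and 10 adjusted over the list alone, list adjusted p = 1.22e-06, adjusted p = 0.294 with an estimated correlation), with Cyp2f2 at -4.90 ± 0.92, Etnppl at -2.93 ± 0.55 and medians of -1.55 on slide 1 and -2.19 on slide 2. Pericentral genes went the other way. Of 19, 6 rose and 0 fell (11 and 0 adjusted over the list alone, list adjusted p = 0.000132, adjusted p = 0.294 with an estimated correlation), with Lhpp at 2.87 ± 0.42 and Gulo at 2.24 ± 0.42. Urea cycle and amino acid genes (adjusted p = 1.58e-05, and adjusted p = 0.336 with an estimated correlation), complement and secreted proteins (adjusted p = 1.74e-05, and adjusted p = 0.294 with an estimated correlation) and oxidative phosphorylation genes (adjusted p = 0.000155, and adjusted p = 0.336 with an estimated correlation) were lower. In these 3 lists 10 of 26, 11 of 28 and 5 of 29 members fell (13, 13 and 7 adjusted over the list alone) and none rose, with Bhmt at -4.72 ± 0.98, C8a at -3.79 ± 0.89 and Sdhb at -1.18 ± 0.23. NRF2 targets were higher (adjusted p = 7.33e-05, and adjusted p = 0.294 with an estimated correlation). Of 19, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with Cbr3 at 3.56 ± 0.61. Glycolysis genes were higher as a list (adjusted p = 0.0195, and adjusted p = 0.336 with an estimated correlation), and of 13, 3 rose and 0 fell (3 and 0 adjusted over the list alone). Of 20 male-biased genes, 0 rose and 6 fell (0 and 7 adjusted over the list alone, list adjusted p = 0.0123, adjusted p = 0.388 with an estimated correlation).

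Targets of β-catenin were higher at 42 than at 28 weeks. Of 16, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a higher list mean on 7 of 7 arrays and medians of 1.00 on slide 1 and 1.27 on slide 2. The list gave adjusted p = 0.000565, and adjusted p = 0.426 with an estimated correlation. With slide as a block it gave 0.00123 (range 1.77e-05 to 0.00647 over the alternatives). Axin2 went from 5.61 ± 0.12 to 7.58 ± 0.65 (1.97 ± 0.59, adjusted p = 0.0282), a call that ended without TCPOBOP 42 weeks replicate 5 (0.0512) or any 1 array at 28 weeks (0.0847 to 0.0969) and on the authors' normalized values (0.106) and with slide as a block (0.0546, range 0.00277 to 0.109). Lgr5, detected on 0 of 3 and 7 of 7 arrays, was at least 1.70-fold higher (adjusted p = 0.0473). That call ended without TCPOBOP 42 weeks replicates 1, 3, 4, 5 or 7 (0.0503 to 0.0783) or any 1 array at 28 weeks (0.114 to 0.157) and with slide as a block (0.0896, range 0.00710 to 0.128). Glul changed by 1.38 ± 0.61 (adjusted p = 0.137), passing with array weights (0.0330, range 0.0330 to 0.257), Tbx3 by 0.91 ± 0.40 (adjusted p = 0.135) and Ctnnb1 by -0.18 ± 0.18 (adjusted p = 0.562). Cyp2e1 changed by 0.24 ± 0.21 (adjusted p = 0.497). This result and the lower list at 28 weeks against controls rest on the same 3 arrays at 28 weeks.

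Markers of sinusoidal cells were lower at 42 weeks. Of 24 endothelial markers, 1 rose and 11 fell (2 and 12 adjusted over the list alone, list adjusted p = 0.000799, adjusted p = 0.426 with an estimated correlation), with Clec4g at -4.17 ± 0.92 and Oit3 at -3.07 ± 0.49. Of 19 Kupffer cell and macrophage markers, 0 rose and 6 fell (2 and 7 adjusted over the list alone, list adjusted p = 0.0132, adjusted p = 0.499 with an estimated correlation and 0.0578 with fry), with the Kupffer cell genes Clec4f at -3.37 ± 0.68, Vsig4 at -3.15 ± 0.78 and Timd4 at -2.19 ± 0.40. Acute phase genes were lower (adjusted p = 0.0219, and adjusted p = 0.499 with an estimated correlation and 0.0725 with fry), and of 27, 1 rose and 6 fell (1 and 9 adjusted over the list alone), with serum amyloid Saa1 at -3.30 ± 0.79, and the call ended with the replicate number as a block (0.0766, range 0.00793 to 0.0766). Red blood cell markers were lower. Of 10, 0 rose and 1 fell (0 and 1 adjusted over the list alone, list adjusted p = 0.0200, adjusted p = 0.336 with an estimated correlation), with Car1 at -1.73 ± 0.27, and the call ended without TCPOBOP 28 weeks replicate 2 (0.0547) and with the replicate block (0.0541, range 0.00581 to 0.0541). Cell cycle genes were higher by a small margin. Of 29, 1 rose and 0 fell (0 and 0 adjusted over the list alone, list adjusted p = 0.0330, adjusted p = 0.716 with an estimated correlation and 0.337 with fry). The call ended without TCPOBOP 42 weeks replicates 1 (0.0970), 2 (0.107) or 5 (0.0689) or TCPOBOP 28 weeks replicates 2 (0.0525) or 3 (0.0772). Gluconeogenesis genes were lower at the edge of the threshold. Of 10, 0 rose and 2 fell (0 and 2 adjusted over the list alone, list adjusted p = 0.0495, adjusted p = 0.426 with an estimated correlation), a call that ended with median scaling (0.0589, range 0.0132 to 0.0589), on the authors' normalized values (0.0558) and without TCPOBOP 42 weeks replicates 2 (0.106), 3 (0.0689) or 5 (0.0876) or TCPOBOP 28 weeks replicates 1 (0.0871), 2 (0.0525) or 3 (0.0504).

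In all, 1715 genes passed the threshold, 797 higher and 918 lower, and 1333 passed with slide as a block. Of the called genes, 99.8% on slide 1 (3 against 1 arrays) and 99.9% on slide 2 (4 against 1 arrays) kept their sign. With median scaling in place of quantile normalization the median of all genes moved to -0.10, and the share of called genes that were higher went from 46.5% to 28.2%. The count was 863, 952 and 823 without TCPOBOP 28 weeks replicates 1, 2 and 3.

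DENA plus TCPOBOP and TCPOBOP alone shared 28 weeks of the agonist and differed by the dose of DENA. They may also differ in tumour tissue, as the labels report tumours in DENA plus TCPOBOP without saying which sample was tumour. Effects of the carcinogen and of tumour tissue cannot be told apart here. In DENA plus TCPOBOP several β-catenin target genes were higher than at 28 weeks of TCPOBOP alone. The glutamate transporter Slc1a2 was higher by 4.76 ± 0.91, the transcription factor Sp5 by 3.40 ± 0.72, Glul by 2.98 ± 0.59 (7.89-fold), Axin2 by 2.74 ± 0.57 and Tbx3 by 2.23 ± 0.39. Glul was at 10.07 ± 1.04 against 7.09 ± 0.36, Axin2 at 8.35 ± 1.28 against 5.61 ± 0.12, and Lgr5, detected on 8 of 9 and 0 of 3 arrays, was at least 2.84-fold higher (adjusted p = 0.00214). Oncofetal genes were higher too (Gpc3 5.71 ± 1.12, Afp 3.30 ± 0.65, Ly6d 4.47 ± 0.80).

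Of 16 β-catenin targets, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a higher list mean on 9 of 9 arrays (adjusted p = 3.36e-08, and adjusted p = 0.278 with an estimated correlation). With slide as a block the list gave 1.74e-07 (range 3.98e-12 to 1.00e-06 over the alternatives), and medians were 2.47 on slide 1 and 1.95 on slide 4. RNA of Ctnnb1 itself changed by -0.02 ± 0.18 (adjusted p = 0.960). Against controls the β-catenin list was not called in DENA plus TCPOBOP (camera adjusted p = 0.0686), while its median was -1.62 at 28 weeks. Much of this contrast thus lies in the same 3 arrays at 28 weeks. Pericentral genes, many of which β-catenin controls in normal liver, were higher as well. Of 19, 9 rose and 0 fell (12 and 0 adjusted over the list alone, list adjusted p = 1.83e-06, adjusted p = 0.211 with an estimated correlation), with Lhpp at 3.18 ± 0.41 and Gulo at 2.51 ± 0.41, while Cyp2e1 changed by 0.22 ± 0.20 (adjusted p = 0.521). Of 17 oncofetal genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, list adjusted p = 1.83e-06, adjusted p = 0.164 with an estimated correlation). Of 19 NRF2 targets, 7 rose and 0 fell (11 and 2 adjusted over the list alone, list adjusted p = 0.000633, adjusted p = 0.325 with an estimated correlation), with thioredoxin reductase Txnrd1 at 1.43 ± 0.20. Of 12 bile duct cell markers, 2 rose and 0 fell (6 and 0 adjusted over the list alone, list adjusted p = 0.00712, adjusted p = 0.278 with an estimated correlation). Of 16 handling stress genes, 2 rose and 0 fell (6 and 0 adjusted over the list alone, list adjusted p = 0.00221, adjusted p = 0.569 with an estimated correlation and 0.172 with fry), with Hsph1 at 2.10 ± 0.42, Klf6 at 1.82 ± 0.40 and medians of 2.47 on slide 1 and 0.30 on slide 4. CAR targets were not called (adjusted p = 0.916, and adjusted p = 0.975 with an estimated correlation), with Cyp2b10 at 0.10 ± 0.13 (adjusted p = 0.646) and Cyp2c55 at -0.05 ± 0.20 (adjusted p = 0.901).

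Genes lower in DENA plus TCPOBOP were led by Mup3 (-5.59 ± 1.24), the carboxylesterase Ces1f (-5.09 ± 0.85), Cyp2f2 (-4.93 ± 0.89) and Car3 (-4.84 ± 0.94). Of 14 periportal genes, 0 rose and 6 fell (0 and 9 adjusted over the list alone, list adjusted p = 2.53e-06, adjusted p = 0.325 with an estimated correlation), with Igf1 at -2.62 ± 0.61 and medians of -2.49 on slide 1 and -1.27 on slide 4. Of 26 urea cycle and amino acid genes, 1 rose and 8 fell (1 and 13 adjusted over the list alone, list adjusted p = 0.000370, adjusted p = 0.403 with an estimated correlation), with urocanase Uroc1 at -2.02 ± 0.37. Complement and secreted proteins were lower, with C4b at -2.78 ± 0.66, and of 28, 0 rose and 6 fell (0 and 8 adjusted over the list alone, list adjusted p = 0.000641, adjusted p = 0.338 with an estimated correlation). Oxidative phosphorylation genes were lower by little, with Ndufa9 at -0.68 ± 0.13, and of 29, 0 rose and 2 fell (0 and 2 adjusted over the list alone, list adjusted p = 0.00712, adjusted p = 0.532 with an estimated correlation). Of 20 male-biased genes, 0 rose and 4 fell (2 and 9 adjusted over the list alone, list adjusted p = 0.00796, adjusted p = 0.351 with an estimated correlation).

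Unlike the bile duct cell markers, several lists of other cell types were lower in DENA plus TCPOBOP. Of 24 endothelial markers, 0 rose and 10 fell (1 and 12 adjusted over the list alone, list adjusted p = 2.81e-05, adjusted p = 0.325 with an estimated correlation), with Ehd3 at -2.42 ± 0.50 and the Wnt amplifier Rspo3 at -2.03 ± 0.38, detected on 6 of 9 arrays. Of 19 Kupffer cell and macrophage markers, 0 rose and 5 fell (0 and 6 adjusted over the list alone, list adjusted p = 0.000641, adjusted p = 0.351 with an estimated correlation), with Timd4 at -1.93 ± 0.39 and the mannose receptor Mrc1 at -1.41 ± 0.28. Of 27 matrix and stellate cell markers, 1 rose and 9 fell (1 and 10 adjusted over the list alone, list adjusted p = 0.00148, adjusted p = 0.532 with an estimated correlation and 0.0710 with fry), with Colec11 at -2.94 ± 0.47 and Ecm1 at -2.65 ± 0.56. MHC class II genes (adjusted p = 0.00996, and adjusted p = 0.532 with an estimated correlation and 0.0710 with fry) and T and NK cell markers (adjusted p = 0.0123, and adjusted p = 0.325 with an estimated correlation) had 2 of 10 and 1 of 11 members falling (3 and 3 adjusted over the list alone) and none rising. The MHC class II call ended with the replicate number as a block (0.393, range 0.00440 to 0.393 over the alternatives).

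In all, 1549 genes passed the threshold, 726 higher and 823 lower, and 1862 passed with slide as a block. Of the called genes, 99.9% on slide 1 (2 against 1 arrays) and 100% on slide 4 (3 against 1 arrays) kept their sign. With median scaling in place of quantile normalization the median of all genes moved to -0.13, and the share of called genes that were higher went from 46.9% to 22.3%. The count was 684, 765 and 741 without TCPOBOP 28 weeks replicates 1, 2 and 3.

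DENA plus TCPOBOP and 42 weeks of TCPOBOP, the arms in which the labels report tumours, differed in few genes. No difference passed for the CAR targets (Cyp2b10 0.06 ± 0.10, adjusted p = 0.763, Cyp2c55 -0.05 ± 0.15, adjusted p = 0.889), or for Afp (0.03 ± 0.49, adjusted p = 0.984), Gpc3 (0.73 ± 0.85, adjusted p = 0.675) and Cyp2e1 (-0.01 ± 0.15, adjusted p = 0.973) though the standard error of Gpc3 leaves room for a difference. The inflammatory caspase Casp1 was lower in DENA plus TCPOBOP (-1.32 ± 0.18, adjusted p = 0.00293), as was Cpne2 (-0.97 ± 0.16), and the transcription factor Zbtb16 was higher (1.23 ± 0.20, adjusted p = 0.0120), as were Usp10 (1.12 ± 0.20) and Dst (1.06 ± 0.19). With slide as a block none of these passed (Casp1 0.161, range 0.000787 to 0.161, Cpne2 0.258, range 0.00947 to 0.258, Zbtb16 0.161, range 0.00433 to 0.161), and with median scaling Usp10 (0.107, range 0.00947 to 0.380) and Dst (0.0948, range 0.00947 to 0.264) did not.

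Targets of β-catenin were higher as a list in DENA plus TCPOBOP (adjusted p = 0.000353, and adjusted p = 0.726 with an estimated correlation and 0.198 with fry). Of 16 members, 1 rose and 0 fell (2 and 0 adjusted over the list alone), the list mean was above the 42-week mean on 7 of 9 arrays, and its median change was 0.76. Tbx3 was the member that passed, at 9.74 ± 0.72 against 8.43 ± 0.55 (1.31 ± 0.29, adjusted p = 0.0252). That call ended without TCPOBOP 42 weeks replicates 1 (0.0587) or 7 (0.0517) and with slide as a block (0.441, range 0.0215 to 0.441). Glul was at 10.07 ± 1.04 against 8.46 ± 1.14 (1.60 ± 0.44, adjusted p = 0.0615), just outside the threshold, and passed without TCPOBOP 42 weeks replicates 3 (0.0227) or 5 (0.0405) or DENA plus TCPOBOP replicates 1 (0.0480), 6 (0.0424) or 8 (0.0472). Axin2 changed by 0.77 ± 0.43 (adjusted p = 0.337), Lgr5 by 0.74 ± 0.29 (adjusted p = 0.173), passing without DENA plus TCPOBOP replicate 6 (0.0469), and Ctnnb1 by 0.16 ± 0.13 (adjusted p = 0.542). With slide as a block the list gave 1.59e-06 (range 1.59e-06 to 0.000562 over the alternatives), but handling stress genes gave 1.36e-11 and cell cycle genes 6.43e-08. On slide 1, the only slide that held both groups, the median change of β-catenin targets was 1.28. Handling stress genes were higher in the same samples. Of 16, 1 rose and 0 fell (7 and 0 adjusted over the list alone, list adjusted p = 2.80e-06, adjusted p = 0.726 with an estimated correlation and 0.198 with fry), with a median of 1.82 on slide 1. Cell cycle genes were lower as a list, and of 29, 0 rose and 0 fell (0 and 5 adjusted over the list alone, list adjusted p = 0.000353, adjusted p = 0.726 with an estimated correlation and 0.313 with fry), with a median of -0.94 on slide 1.

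In all, 205 genes passed the threshold, 107 higher and 98 lower in DENA plus TCPOBOP, and 2283 had an unadjusted p under 0.05. With slide as a block in limma the count was 0, with 1172 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.161. On slide 1, 99.5% of the called genes kept their sign (2 against 3 arrays). They were called on these same arrays, so this agreement does not weigh against a slide effect. With median scaling 19 genes passed, 10.5% of them higher, against 52.2%. The count was 90, 106, 545 and 123 without TCPOBOP 42 weeks replicates 1, 2, 3 and 6. It was 114, 126 and 126 without DENA plus TCPOBOP replicates 3, 4 and 7.

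**Figure D3:**
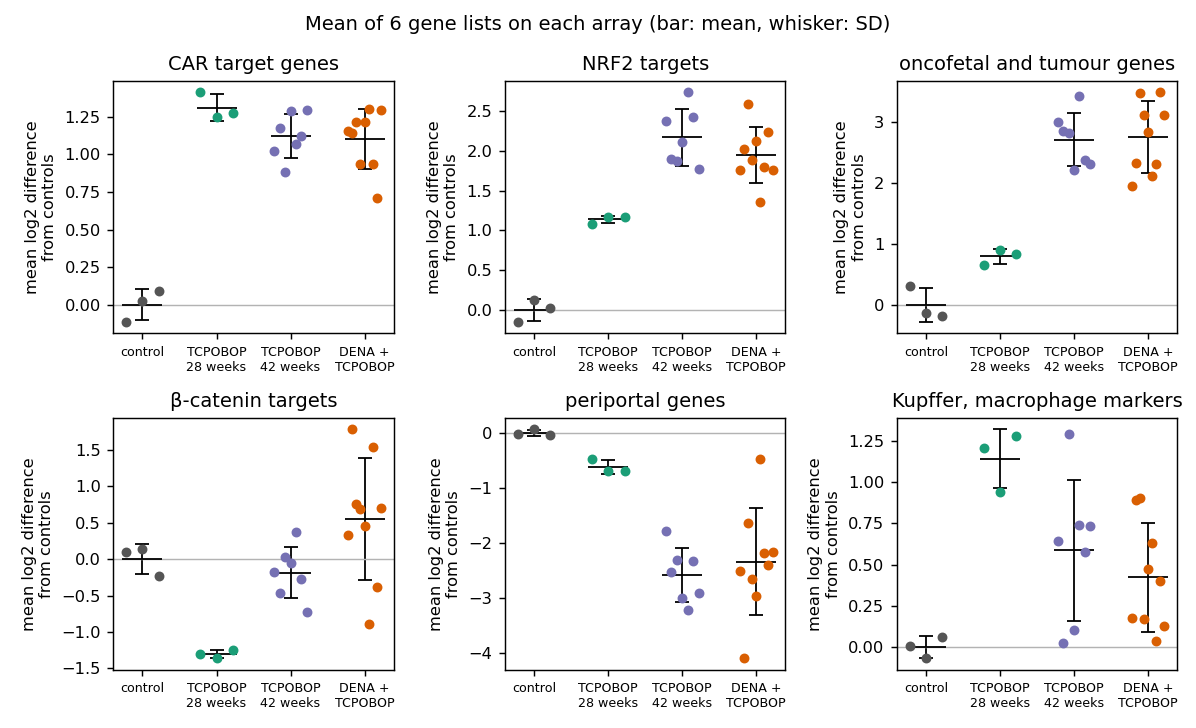
Mean log2 difference from the controls of 6 gene lists on each array, by group. Points are arrays, bars the group mean and whiskers the SD. CAR targets lie above the control mean on every treated array, and β-catenin targets lie lowest at 28 weeks of TCPOBOP (median change of -1.62 against controls).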

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

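The slide and cell-type tests below, and the counts over other groupings of the arrays, were chosen only after the result was seen, while the handling test and the tests of replicate 6 were chosen before. Arrays far from their group were sought in 296 sets of values: 108 genes named in the text, 38 list means, the share of detected probes and component 1, each in the groups of 7 and 9 arrays. An array counted as apart where its gap to the next, divided by the group's range, passed Dixon's 95% limit. This held in 32 sets, where chance (about 1 in 20) would give 14.8, and 13 of them concern DENA plus TCPOBOP replicate 6 and 9 replicate 2 of the same group.

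DENA plus TCPOBOP replicate 6 was apart as the lowest in Abcc4 (0.595), Axin2 (0.502), Cyp1a2 (0.616), Cyp2e1 (0.588), Gulo (0.634), Sidt1 (0.535) and Slc13a3 (0.595). It was apart as the highest in Cbs (0.598), Dct (0.819), Prss2 (0.722), Uroc1 (0.573), the urea cycle and amino acid list (0.497) and component 1 (0.501). Replicate 2 was apart as the highest in Atf3 (0.618), Gadd45b (0.513), Hsph1 (0.562), Klf6 (0.571) and the MAPK feedback (0.787), glycolysis (0.550), unfolded protein response (0.539), hypoxia (0.585) and handling stress (0.651) lists, largely stress-response genes. Replicate 8 was apart in Sult2a8 (0.531, highest). Among TCPOBOP 42 weeks arrays, replicate 3 was apart in Bdh2 (0.574, highest), Bhmt (0.606, highest), Cyp2c55 (0.617, lowest) and Dct (0.727, highest), replicate 6 in Cyp2e1 (0.620, lowest) and the cholesterol synthesis list (0.574, lowest), replicate 2 in Dst (0.577, lowest), replicate 5 in Cbr3 (0.651, highest) and replicate 7 in Mup3 (0.632, lowest).

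DENA plus TCPOBOP replicate 6 lay between its group and TCPOBOP 28 weeks on component 1. A poor array stays open. Its share of detected probes, 40.3%, lay inside the 38.3% to 41.8% of the other 8. That share was the lowest on slide 3 (others 40.5% to 41.8%), and its raw median intensity, 89.8, was the lowest of all arrays. For a sample of another group, r with its own group minus the highest r with another was -0.116, which met the criterion set beforehand, but r with TCPOBOP 28 weeks was 0.229, far below the 0.626 to 0.674 of that group's own arrays, which argues against it by a criterion added after the value was seen. A mixture with surrounding tissue, for which TCPOBOP 28 weeks only stands in, would pull genes alike, yet the array lay 0.277 of the way to its group for genes higher there and 0.623 for genes lower, and the difference of 0.346 exceeds the limit of 0.2 set beforehand by more than the SD of the other 8 arrays (0.113), though an allowance of 2 SD, tried after the value was seen, would leave it open. A sample from outside these groups, other admixed tissue and a biologically different lesion were not tested, and the last may be the cause only as a hypothesis.

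Targets of β-catenin were higher in DENA plus TCPOBOP than at 42 weeks of TCPOBOP. The list call ended with an estimated correlation (camera adjusted p = 0.726) and with fry (0.198), so chance spread between these arrays stays open. A difference between slides as the whole cause is argued against, though weakly, by slide 1, which held both groups (2 against 3 arrays). The list's median difference there was 1.28 (robust SE 0.339), with 14 of 16 members higher. That error is over members, which may move together, and not over arrays. The arrays there included DENA plus TCPOBOP replicate 2, which was apart in handling stress genes, so slide 1 cannot separate handling from the groups. Handling of the tissue stays open, since handling stress genes were higher in the same samples: over 16 arrays, after centring within groups, the correlation of the list means was r = 0.260 (permutation p = 0.435) and Spearman's rho = -0.171 (permutation p = 0.534), with r = -0.536 without the 2 farthest arrays. The carcinogen and the weeks of TCPOBOP differ together between these groups, and the share of tumour tissue per sample is not given, so none was tested, and β-catenin activation in more of the DENA samples may be 1 of several explanations.

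The same list was lower at 28 weeks of TCPOBOP than in controls. A larger share of other cell types stays open as part of the cause, since Kupffer cell and macrophage markers (camera adjusted p = 1.60e-07) and MHC class II genes (3.02e-05) were higher. As the whole cause it is argued against, unless bright secreted genes hide a fall. The median change of complement and other secreted hepatocyte genes lay above that of the list by 1.34 (robust SE 0.517, medians -0.28 and -1.62). The robust SEs here are over list members, which may move together, and not over arrays. A slide difference as the whole cause is argued against too: with slide as a block the list's median was -1.82 (robust SE 0.574, list adjusted p = 0.00265), although on the slides with both groups, 1 array of each, the medians of -1.69 (robust SE 0.563) and -1.03 (robust SE 0.611), weighed first, would not decide it, the latter lying within 2 of its errors of 0. The call itself ended with fry (0.145), so chance spread between these few arrays stays open. Age could differ too, as the labels call the controls age-matched without saying to which of the times, and a lower β-catenin activity under the agonist is a candidate explanation that was not tested.

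Differences between treated groups were tested directly. DENA plus TCPOBOP differed from 42 weeks of TCPOBOP in 205 genes and 3 lists (β-catenin list adjusted p = 0.000353), DENA plus TCPOBOP from 28 weeks in 1549 genes and 16 lists (adjusted p = 3.36e-08), and 42 from 28 weeks in 1715 genes and 16 lists (adjusted p = 0.000565). With an estimated correlation none of these list calls held, the lowest adjusted p being 0.726, 0.164 and 0.134 in that order. Of 3555 detected probes without a gene symbol, 950 changed at 42 weeks, 795 in DENA plus TCPOBOP and 190 at 28 weeks against controls. Other groupings of the same arrays were counted to ask whether chance gives as many genes, with 100 groupings for all but 28 weeks against controls. Only 1 of 100, the real grouping, gave as many for 42 weeks against controls (3872 genes, highest other 388) and DENA plus TCPOBOP against controls (3174, 614). The same held for DENA plus TCPOBOP against 42 weeks (205, 13) and 28 weeks (1549, 110), and for 42 against 28 weeks (1715, 22). This argues against a chance division of separate samples. If samples shared a mouse, which the labels leave open, that share would not hold. These groupings ignore slide, and with slide as a fixed block limma called 0 of the 205 genes between DENA plus TCPOBOP and 42 weeks (1172 genes at an unadjusted p under 0.05, smallest adjusted p = 0.161), so a slide effect on those genes is not excluded. For 28 weeks against controls the 10 groupings are too few for a share under 0.05 (703 genes, highest other 0).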

How the results depend on the processing

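For gene lists, cyclic loess, median scaling, no background correction and left-out arrays were tried only after the results were seen, and the other alternatives were planned. Over all settings, 8013 values of named genes kept direction and side of the threshold, 473 lost a call, 25 gained one and 50 changed sign. For single lists these numbers were 1443, 125, 16 and 3. Among counts, 182 stayed within 1.5 times and 26 did not. Genes changed between DENA plus TCPOBOP and 42 weeks numbered 19 with median scaling, 127 with slide as a random block and 84 when only these groups were fitted. In limma, slide as a fixed block gave 0, with 1172 at an unadjusted p under 0.05. With median scaling 1078 changed between 42 and 28 weeks. For 28 weeks against controls 1719 changed when only these groups were fitted and 2030 with array weights. Array weights also gave 2778 between DENA plus TCPOBOP and 28 weeks and 2771 between 42 and 28 weeks.

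Of the 76 list calls, 6 held with an estimated correlation, and 73 to 85 were made with 1 array left out. Genes changed then numbered 2723 to 3996 (42 weeks vs control), 2246 to 3328 (DENA plus TCPOBOP vs control), 441 to 512 (28 weeks vs control), 90 to 545 (DENA plus TCPOBOP vs 42 weeks), 684 to 1848 (DENA plus TCPOBOP vs 28 weeks) and 823 to 1874 (42 vs 28 weeks). Where a group of 3 keeps 2 arrays, these are assumed to vary like the other groups.

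The changes that turned sign were not past the threshold, before or after. They were, under cyclic loess Cyp2e1 -0.0262 (42 weeks vs control), Cyp2e1 -0.0182 (DENA plus TCPOBOP vs control), Cyp2e1 0.00802 (DENA plus TCPOBOP vs 42 weeks), Cyp2c55 0.0156 (42 vs 28 weeks). Further, with median scaling Cyp1a2 -0.0288 and Cyp2b10 -0.10 (DENA plus TCPOBOP vs 42 weeks). Next, with the mean of probes Cyp2b10 -0.34 and Nr1i3 -0.00958 (DENA plus TCPOBOP vs 42 weeks), Ctnnb1 0.20 and Cyp2b10 -0.0152 (DENA plus TCPOBOP vs 28 weeks), Ctnnb1 0.0676 (42 vs 28 weeks). Next, with slide as a fixed block Axin2 -0.13 and Cyp2e1 -0.0424 (42 weeks vs control), Ctnnb1 -0.0907 and Cyp2e1 0.12 (DENA plus TCPOBOP vs 42 weeks), Cyp2c55 0.0356 (42 vs 28 weeks). Next, with slide as a random block Cyp2c55 0.00179 (42 vs 28 weeks). Next, with the replicate number as a block Afp -0.22 (DENA plus TCPOBOP vs 42 weeks), Cyp2c55 0.0381 (42 vs 28 weeks). Next, with array weights Afp 0.0538 (28 weeks vs control), Ctnnb1 0.0203 (DENA plus TCPOBOP vs 28 weeks), Cyp2c55 0.0142 (42 vs 28 weeks). The β-catenin list at 42 weeks against controls changed direction with slide as a fixed block (adjusted p = 0.721) and with 1 array left out (adjusted p = 0.75 to 0.98), without being called. With 1 array left out the log2 changes below crossed 0. For DENA plus TCPOBOP vs 42 weeks, Afp -0.27 to 0.27, Cyp2e1 -0.0629 to 0.0798, Nr1i3 -0.000216 to 0.25, Cyp1a2 -6.89e-05 to 0.17 and Cyp2c55 -0.16 to 0.00278. In 42 vs 28 weeks, Cyp2c55 -0.0576 to 0.10 and Cyp2b10 -0.0595 to 0.11. In DENA plus TCPOBOP vs 28 weeks, Ctnnb1 -0.13 to 0.11. In 28 weeks vs control, Cyp2e1 -0.31 to 0.0946 and Afp -0.56 to 0.38. In DENA plus TCPOBOP vs control, Cyp2e1 -0.0538 to 0.32 and Tbx3 -0.0715 to 0.66. In 42 weeks vs control, Cyp2e1 -0.0394 to 0.33. Where the text names no cause, the cause was not tested.

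Signal over background limits what can be seen. Per array, 34.8% to 42.6% of probes were detected. Genes undetected in a group have only a lower limit to their change. In simulated data with equal spread in all groups, 4% to 16% of changes of 0.5 on the log2 scale were recovered. At the bright end all arrays share a maximum of 15.51 after normalization, and Cyp2b10 and Cyp2e1 lay near it after TCPOBOP. So did Cyp1a2 in DENA plus TCPOBOP, except on replicate 6.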

Other observations

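Some of the largest rises concern genes not described above. The membrane protease Tmprss7 rose by 5.56 ± 0.28 at 28 weeks of TCPOBOP, 6.43 ± 0.23 at 42 weeks and 5.97 ± 0.22 in DENA plus TCPOBOP against controls, of which 1 of 3 detected it, and the RNA transporter Sidt1 by 5.30 ± 0.42 at 28 weeks and 6.32 ± 0.34 in DENA plus TCPOBOP. The kidney salt transporter Slc12a1 was detected on no control array and was at least 84.4-fold higher at 42 weeks. Against 28 weeks of TCPOBOP, the osteocalcin gene Bglap2 was higher by 4.67 ± 0.67 in DENA plus TCPOBOP, and the glutathione transferase Gstp2 by 4.72 ± 0.54 there and 4.92 ± 0.56 at 42 weeks.

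Pancreatic acinar markers were called as a list in each treated group against controls, though no acinar cell content follows from it. Of 6 measured, 2 rose and 0 fell (2 and 1 adjusted over the list alone, list adjusted p = 0.00634, adjusted p = 0.0694 with an estimated correlation) at 28 weeks, 2 rose and 0 fell (3 and 0 adjusted over the list alone, list adjusted p = 0.0428, adjusted p = 0.187 with an estimated correlation) at 42 weeks and 1 rose and 0 fell (1 and 0 adjusted over the list alone, list adjusted p = 0.0284, adjusted p = 0.181 with an estimated correlation) in DENA plus TCPOBOP. The list mean was higher on 3 of 3 arrays, 7 of 7 arrays and 9 of 9 arrays. The largest rise was that of the lipase-related gene Pnliprp1 (5.92 ± 0.57, 6.31 ± 0.48 and 6.25 ± 0.47). Trypsinogen Prss2 was at least 2.02-fold higher at 28 weeks, and elastase Cela1, also expressed outside the pancreas, rose by 1.59 ± 0.46 at 42 weeks (adjusted p = 0.0106). That call ended without control replicate 3 (0.0595) and with slide as a block (0.0503, range 0.000497 to 0.0503).

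Of the 38 lists, 12 were called in no comparison. Their lowest adjusted p over the 6 comparisons was 0.0581 for MAPK feedback, 0.150 for YAP targets, 0.580 for adipocyte markers, 0.432 for bile acid metabolism, 0.0979 for cholesterol synthesis, 0.0624 for circadian clock, 0.0683 for fatty acid oxidation, 0.224 for female-biased liver genes, 0.0858 for lipogenesis, 0.372 for neutrophil markers, 0.402 for p53 targets and 0.131 for unfolded protein response. A list that was not called is not shown to be unchanged.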
